A study of Mus musculus with 8 samples.

How the data were processed

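RNA was measured in splenic B cells of wild-type mice and of mice homozygous for the 3'RR, hs3b-hs4 or 3'PAL deletion, on a mixed background that the labels give as 129/C58BL/6. Cells were isolated on a density gradient and by removal of CD43-positive cells, and were used at once or cultured for 48 hours with 5 µg/mL lipopolysaccharide and separated on a gradient again. Per the labels, ribosomal RNA was depleted from total RNA, and stranded libraries were sequenced as paired-end reads. Each of the 8 libraries came from a pool of 4 animals, with 1 library for each of 4 genotypes in each of 2 states.

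The gene table holds raw counts per gene symbol, made by the authors with STAR 2.4.0a alignment to GRCm38 (mm10) and featureCounts of Subread 1.4.6-p1, as named in the submitters' processing notes. The transcript tables hold estimated counts and, in a separate table, TPM (transcript abundance scaled to length and library size), both deposited as made by the authors with kallisto 0.42.3. SAMtools and bedtools are also named in these notes. The annotation version, the strand setting and whether reads or fragments were counted are not given in the sources used here. In the TPM table some header names did not match the content of their columns, and columns were assigned by their content.

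The gene table listed 41249 genes, of which 25075 had a count. Total counts per library ran from 17883683 to 28785192, so a floor of 3 counts lay between 0.1 and 0.15 CPM (counts scaled to library size). A single entry without a gene name held 0.0062 to 0.034% of a library's counts and was left out, and 93 spike-in entries had no count in any library. The transcript tables covered 88198 transcripts of 30617 genes. Immunoglobulin and T cell receptor V, D and J segments were counted as classes and not named.

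Counts were scaled by the trimmed mean of M values (TMM, factors from 0.925 to 1.09) with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr function, which left 14744. Stimulation and each mutant over both states were tested in 1 quasi-likelihood fit with genotype and state as terms (3 residual degrees of freedom, biological coefficient of variation 16%). This fit assumes that a mutant change is the same in both states and does not test whether it is. A gene near 0 in stimulated cells can be called from the resting libraries. Genotypes without and with hs3b and hs4 were compared within each state in a fit with 4 groups of 2 libraries (4 residual degrees of freedom, biological coefficient of variation 25.8%), in which different genotypes serve as replicates. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05.

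Within a state a mutant library was compared with the wild-type library without a test, by a log2 ratio of at least 1 on log2(CPM + 1) and at least 10 CPM in the higher library. Intervals on a CPM value are exact 95% Poisson intervals, and those on a ratio are exact conditional binomial intervals. A gene with no count in a mutant library is given as at least N-fold lower against the floor of 3 counts in that library. Membrane and secreted Ighm transcripts were told apart by their coding exons, and their shares were compared between states by an exact sign-flip test over the 4 genotypes.

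The 26 gene lists were the IgH constant genes, light chain constant genes, IgH neighbours, plasmablast regulators and markers, secretory pathway and unfolded protein response, B cell identity, class switch and hypermutation, cell cycle, NF-kB and TLR4 response, glycolysis and nutrient uptake, ribosome biogenesis, cholesterol synthesis, interferon response, immediate early and stress genes, marginal zone genes, B-1 genes, sex-linked genes and 9 lists of cell type markers (T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, megakaryocytes and platelets, endothelial and stromal cells, and plasma cells). The camera test of limma 3.58.1 was run on 24 of them, without the sex-linked and IgH constant genes, with a preset correlation of 0.01 and again with a correlation estimated for each list. List medians within a state were set against 10000 random lists of genes of similar level.

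The comparisons, tests, lists and naming rule were set before the data were examined. The plan left only the sex-linked list out of the camera test, so leaving out the IgH constant genes was not part of it. Named for stimulation were the 8 largest rises and 8 largest falls with mean log2 CPM of at least 5 and the same direction in all 4 genotypes, for each mutant over both states the 5 largest of each direction with mean log2 CPM of at least 3 and the same direction in both states, and within a state the 4 largest of each direction by the size rule. At most 4 members of a list with the lowest adjusted p were named, and the IgH and light chain constant genes throughout. Genes with clone or predicted-gene names were counted but not named. Some genes that meet this rule are not reported here.

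Each test was checked on simulated data with the dispersions of these libraries and 200 changed genes. At 1.5-fold, 2-fold and 4-fold the stimulation test recovered 25.4%, 70.1% and 86.4% of changed genes and called 14 unchanged ones. The test of the 3'RR deletion recovered 1.49%, 49.3% and 75.8% (10 unchanged called), that of the hs3b-hs4 deletion 4.48%, 32.8% and 78.8% (8 unchanged called) and that of the 3'PAL deletion 1.49%, 40.3% and 80.3% (9 unchanged called). For the genotypes without against with hs3b and hs4 the recovery was 0%, 7.46% and 56.1% in stimulated cells (3 unchanged called), 0%, 8.96% and 68.2% in resting cells (1 unchanged called) and 0%, 0% and 31.8% for the difference between states (3 unchanged called).

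The alternatives tried were DESeq2 size factors within edgeR, TMM without immunoglobulin genes, scaling by library size alone, no low-count filter, the DESeq2 1.42.0 Wald test, kallisto counts summed per gene and rounded to whole numbers, fits without the genotype term or with a mutant and wild-type libraries only, leaving out libraries, minimum levels of 5 and 20 CPM, a pseudocount of 0.5 and removal of receptor segments. Leaving out a single resting library in the tests of a mutant over both states, and removing markers of other cell types within a state, were chosen after seeing the data.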

Results

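RNA was measured in mouse splenic B cells of 4 genotypes, either freshly isolated (resting) or after 48 hours of culture with 5 µg/mL lipopolysaccharide (stimulated), a bacterial cell wall component that activates B cells through the receptor TLR4. The genotypes were wild-type and homozygous for 1 of 3 deletions in the 3' regulatory region (3'RR), the enhancer cluster downstream of the immunoglobulin heavy chain (IgH) constant gene Igha. The 3'RR deletion removes the whole cluster, including the hs3b and hs4 enhancers, and the hs3b-hs4 deletion removes these enhancers from an otherwise intact cluster. The 3'PAL deletion is known to disturb the palindromic arrangement of the cluster while its enhancers are preserved, and the labels give only its name. The comparisons ask which transcripts, at the IgH locus and elsewhere, differ when the whole cluster, part of its enhancers or its arrangement is lost, and how cells of each genotype respond to stimulation. Each genotype and state gave 1 library, prepared from B cells of 4 animals, so that 8 libraries were compared. Whether the resting and stimulated pools of a genotype came from the same animals is not given in the sources used here.

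The gene counts summed to between 17883683 (wild-type resting) and 28785192 (wild-type stimulated) per library. Across genes, the log2 levels of 2 libraries of the same state correlated at 0.957 to 0.98 (Pearson, resting) and 0.972 to 0.987 (stimulated), against 0.825 to 0.886 between states. Genes are not independent replicates, so these values only describe the libraries. The resting libraries differed in their content of red cell transcripts. The 4 adult globin genes together stood at 2989 CPM (counts scaled to library size) in wild-type, 12538 in 3'RR deletion, 10344 in hs3b-hs4 deletion and 20414 in 3'PAL deletion resting cells, and at 10.14, 153.8, 42.7 and 237.4 CPM in the stimulated cells of the same genotypes. The wild-type resting library also held 1.94% of its counts in AY036118, a gene model that overlaps ribosomal RNA sequence, where the other 7 libraries held at most 0.0842%. It held 15.4% of the estimated transcript counts in Lars2, against at most 1.7% elsewhere.

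The IgH constant genes lie on chromosome 12 of the GRCm38 build, on the minus strand, from Ighm (113418950 to 113422730) to Igha (113258768 to 113260236), the constant gene next to the deleted enhancers. The deleted segments hold no gene of the count table, so the counts of these genes are an outcome and do not check the labels. In 3'RR deletion cells every IgH constant gene was lower than in wild-type cells of the same state, although Ighe, with 4 counts in stimulated wild-type cells, was too rare there to compare. Ighm, which encodes the heavy chain of IgM, stood at 1253 CPM against 2799 CPM in resting cells (ratio 0.448, 95% interval 0.442 to 0.454) and at 3634 against 9720 CPM in stimulated cells (ratio 0.374, 0.371 to 0.377). The IgG genes were close to absent: Ighg3, Ighg1, Ighg2b and Ighg2c together had 16 counts in resting and 6 counts in stimulated 3'RR deletion cells, against 1186 and 4294 in wild-type cells, ratios of 0.00916 (0.00522 to 0.0149) and 0.00147 (0.00054 to 0.00321). Ighg1 had no count in resting 3'RR deletion cells, at least 69.7-fold lower than in wild-type cells, and Ighg2c had none in stimulated cells, at least 54.4-fold lower, both against a floor of 3 counts in that library. Igha, which encodes the heavy chain of IgA, had a ratio of 0.358 (0.293 to 0.435) in resting cells. Each interval covers counting error only, since each value comes from 1 library and PCR copies are not independent molecules.

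In hs3b-hs4 deletion cells IgG transcripts were lower than in wild-type cells, except Ighg1 in resting cells (ratio 1.11, 0.891 to 1.38; 0.656 with kallisto counts). Their summed level was 0.251 times wild-type in resting cells (0.224 to 0.282) and 0.221 times in stimulated cells (0.205 to 0.237), and Ighg3 was 0.0463 times (0.0319 to 0.0651) and 0.233 times (0.212 to 0.254) wild-type. Ighm as a whole was not lower, at 1.32 times wild-type in resting cells (1.3 to 1.33) and 1.13 times in stimulated cells (1.12 to 1.14), and Igha was 2.03 times wild-type in resting cells (1.78 to 2.33). The resting Ighm value was carried by the secreted transcript, with 70969 estimated counts against 18211 in wild-type cells. The membrane transcript was lower there, with 26432 against 38994 estimated counts. Ighd, measured from estimated transcript counts only, was 0.481 times wild-type in resting hs3b-hs4 deletion cells and 0.431 times in resting 3'RR deletion cells. In stimulated cells it was 0.998 times wild-type in hs3b-hs4 deletion (0.936 to 1.06), 0.799 times in 3'RR deletion and 1.75 times in 3'PAL deletion cells. In 3'PAL deletion cells Ighm was 0.879 times wild-type in resting cells (0.868 to 0.889) and 0.679 times in stimulated cells (0.675 to 0.683). Ighg3 stood at 35 CPM in stimulated 3'PAL deletion cells against 99.6 CPM in wild-type cells (ratio 0.352, 0.327 to 0.378), whereas in resting cells its ratio was 1.13 (1.02 to 1.26) and became 0.993 with scaling by library size alone. Ighg2b was higher in stimulated 3'PAL deletion cells, 1.6 times wild-type (1.48 to 1.72), while the summed IgG genes were lower, 0.845 times in resting (0.78 to 0.915) and 0.685 times in stimulated cells (0.654 to 0.718). Ighg2c was low in all 3 mutants, at 0.0675 times wild-type in resting 3'PAL deletion cells (0.0392 to 0.109) and 0.0568 times in resting hs3b-hs4 deletion cells (0.0319 to 0.0944). Of 42 ratios over 7 IgH constant genes, 3 mutants and 2 states, 27 were at or below 0.5. These include stimulated Ighe in 3'RR deletion (0 against 4 counts) and hs3b-hs4 deletion cells (1 against 4 counts), which is too rare to compare. Reads of the IgG genes, which resemble each other, may be split between them, so the summed values are firmer than those of each gene.

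Igkc, the kappa light chain constant gene, was between 1.5 and 2.45 times wild-type in each of the 6 mutant libraries, and 1.91 times (1.89 to 1.93) in stimulated 3'RR deletion cells. Iglc2, a lambda light chain constant gene, was 1.02 times wild-type in 3'RR deletion, 1.33 times in hs3b-hs4 deletion and 0.994 times in 3'PAL deletion resting cells, and 2.02, 1.24 and 1.44 times in stimulated cells of the same genotypes. Igj, which encodes the joining chain of secreted IgM, was between 2.79 and 7.1 times wild-type. Igj was singled out after its values were seen, and all of these ratios share the wild-type library of their state.

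**Figure D1:**
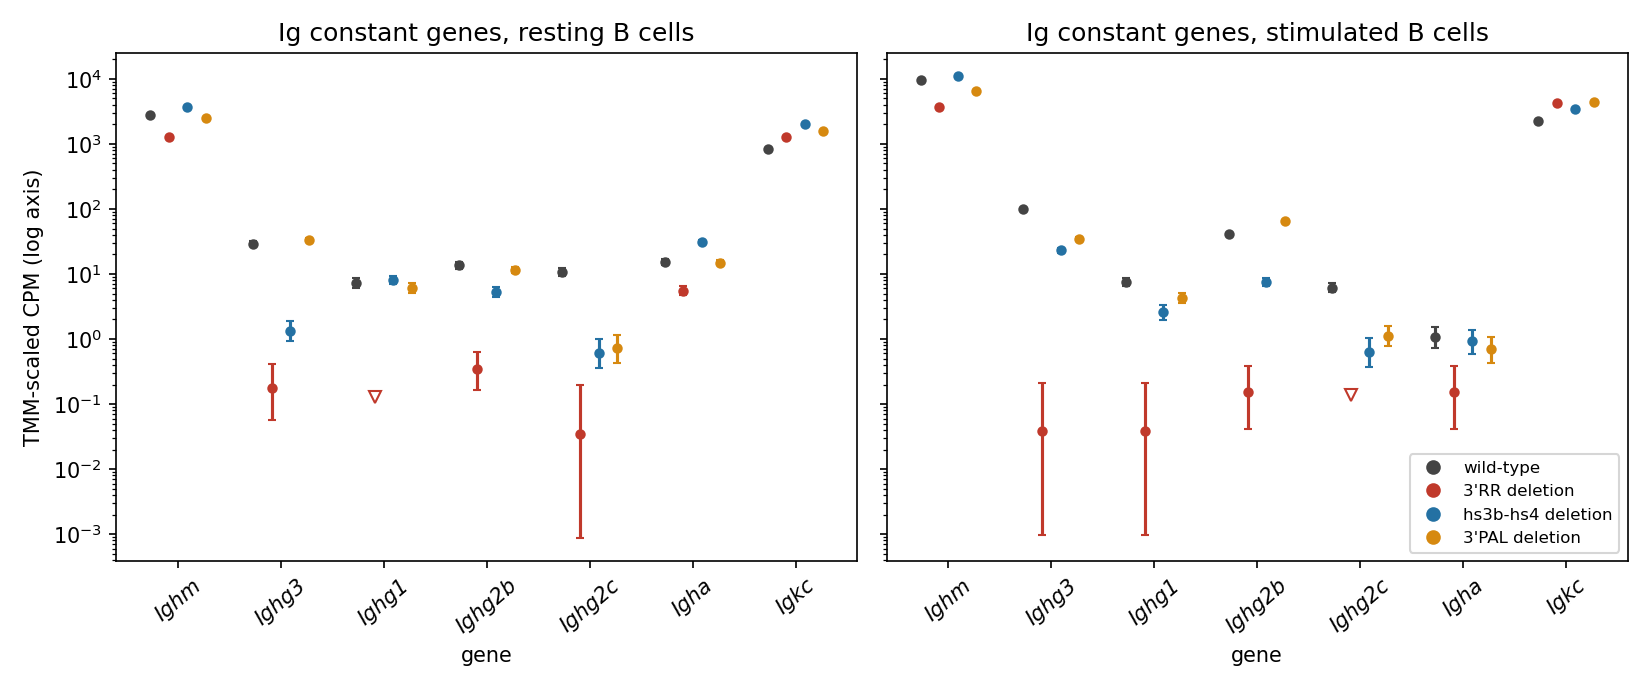
TMM-scaled CPM (log axis) of IgH constant genes and Igkc in each resting (left) and stimulated (right) library, coloured by genotype, with exact 95% Poisson intervals that cover counting error only, and open triangles at the upper end of this interval where no count was seen. The 3'RR deletion points lie far below wild-type for the IgG genes and lower for Ighm, which stood at 3634 CPM against 9720 CPM in stimulated wild-type cells.

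The transcript table separates the membrane and secreted forms of Ighm, which differ in their last coding exons (6 coding exons in the membrane and 4 in the secreted transcript). The secreted form made up 35.1% of Ighm TPM (transcript abundance scaled to length and library size) in wild-type resting cells and 83.4% in wild-type stimulated cells. In 3'RR deletion cells the shares were 26.8% and 64.4%, in 3'PAL deletion cells 28.6% and 71.6%, and in hs3b-hs4 deletion cells 75.7% and 86.6%. Secreted Ighm in stimulated 3'RR deletion cells stood at 1762 TPM against 6769 TPM in wild-type (ratio 0.26), while the membrane form stood at 974 against 1348 TPM (ratio 0.723). In TPM, the secreted form in resting hs3b-hs4 deletion cells was 4.96 times and the membrane form 0.861 times wild-type. All 6 plasma cell markers were higher in that library (median log2 ratio 0.89), but also in resting 3'PAL deletion cells (0.42), where the secreted form was 1.09 times wild-type in TPM, and 5 of 6 in resting 3'RR deletion cells (0.49), where it was 0.624 times wild-type. TPM are not TMM-scaled. With TMM-scaled kallisto counts Ighm as a whole was 1.28 times wild-type in resting hs3b-hs4 deletion, 0.898 times in 3'PAL deletion and 0.466 times in 3'RR deletion cells. Both forms had TPM ratios above these values in 3'PAL and 3'RR deletion cells. Resting ratios in TPM, and the direction of the ratio of 1.09, are therefore uncertain, while the shares do not depend on scaling. Over the 4 genotypes the secreted share was higher after stimulation by 35 percentage points on average (SD 16.6, n = 4). All 4 differences had the same sign, the most extreme outcome of an exact two-sided sign-flip test, which cannot reach the 0.05 threshold with 4 genotypes. These are estimates by the authors' transcript quantification, and their depth per transcript end is not given in the sources used here.

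**Figure D2:**
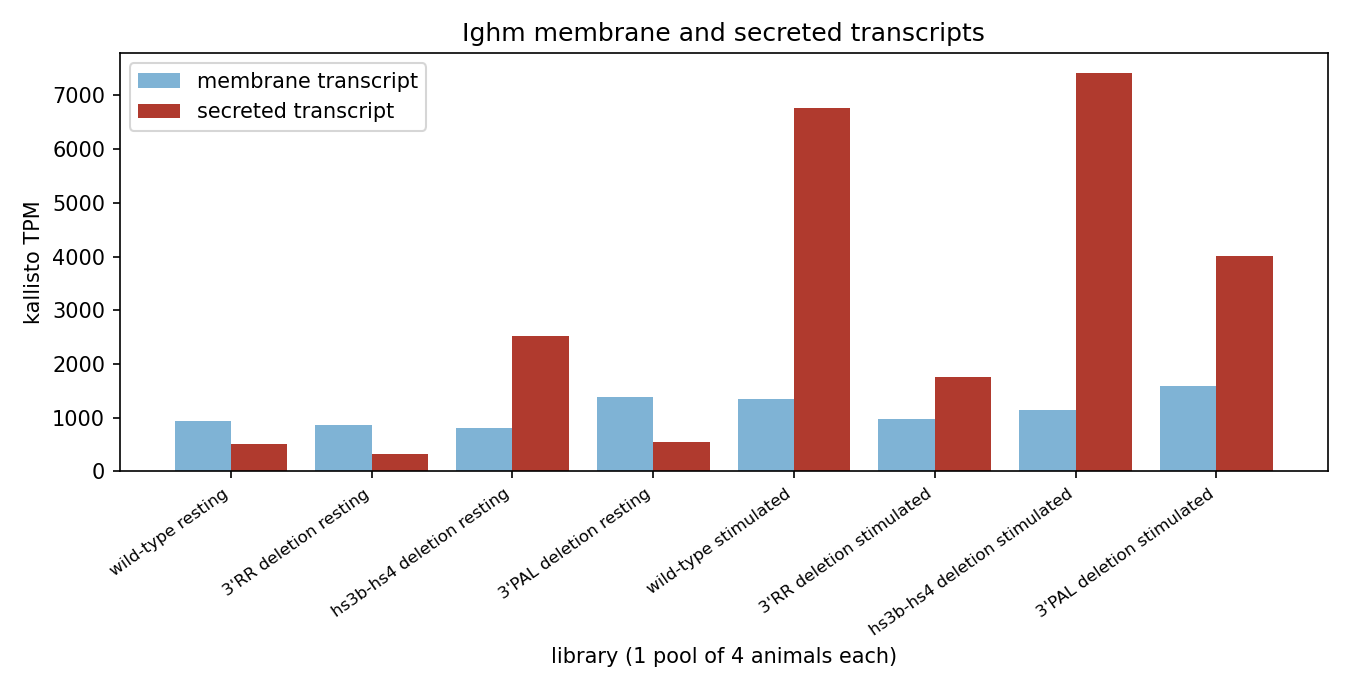
TPM of the membrane and the secreted Ighm transcript in each of the 8 libraries, 1 pool of 4 animals each, with no error bars because there is 1 library per genotype and state. The secreted form is the larger in the 4 stimulated libraries and, among resting libraries, in hs3b-hs4 deletion cells (2520 against 810 TPM).

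Stimulation for 48 hours was tested over all 8 libraries, with genotype as a term. Most or all genes of the lists for cell division, cholesterol synthesis, protein secretion and ribosome production rose. Most or all genes of the lists for resting B cell identity, marginal zone B cells and the immediate early response fell. None of these lists stayed called by the camera test with an estimated correlation, as given below. All 30 cell cycle genes rose, among them Gins2, a subunit of the replication helicase (log2 fold change 3.32 ± 0.127 SE, edgeR adjusted p = 3.6e-06), and Cdc45 (3.58 ± 0.175, adjusted p = 6.7e-06). All 21 cholesterol synthesis genes rose, led by Idi1 (3.50 ± 0.0854, adjusted p = 1.8e-06) and Sqle, squalene epoxidase (3.03 ± 0.0919, adjusted p = 2.1e-06). In all, 10282 of 14744 genes tested changed (5259 higher, 5023 lower; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 10650 at an unadjusted p under 0.05 where chance would give 737. Each error in the text beside a log2 fold change is a standard error from this kind of model.

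The largest rises among well expressed genes were Zbtb32, a transcriptional repressor of activated B cells (5.83 ± 0.27, edgeR adjusted p = 6e-06), from 1.93 to 5.01 CPM in resting libraries to 153.6 to 186.5 CPM in stimulated ones, and the chemokine gene Ccl22 (4.50 ± 0.772, adjusted p = 0.0014). The next 6 were Shcbp1, Ccnb1, Bub1b, Hmmr, Nek2 and Rrm2, with log2 fold changes from 3.72 to 4.18. Ccnb1 encodes the mitotic cyclin B1, Bub1b a spindle checkpoint kinase and Rrm2 a subunit of ribonucleotide reductase. Among the largest falls were Vcam1, Slc40a1, Slc4a1, Csf1r, Tgm2, Hbb-bt and Hba-a1. Slc4a1, the red cell anion exchanger, went from 16.3 to 434 CPM in resting libraries to at most 0.386 CPM after culture, and Csf1r, the macrophage growth factor receptor, from between 50.2 and 251 CPM to at most 0.53 CPM. Fitted fold changes of genes this close to 0 depend on the prior count. Hba-a1 and Hbb-bt have near-identical copies, so their separate counts are uncertain.

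Among the fixed lists, members named because they moved against their list were chosen after their values were seen. Of the 26 secretory pathway and unfolded protein response genes 22 rose and 3 fell. Pdia6 (2.30 ± 0.0937, edgeR adjusted p = 4.4e-06) and Manf (2.33 ± 0.0989, adjusted p = 4.9e-06), both proteins of the endoplasmic reticulum, rose. The 3 that fell were Ddit3 and Atf4, transcription factors of the stress response, and the chaperone Dnajb9. Of 19 plasmablast regulators and markers 12 rose and 2 fell, with Xbp1, the transcription factor of antibody-secreting cells (2.32 ± 0.134, adjusted p = 1.2e-05), and Il10 (3.21 ± 0.19, adjusted p = 1.2e-05) among the rises and Irf4 and Zbtb20 as the falls. Of the 6 plasma cell markers 4 rose, including Prdm1 (2.72 ± 0.2, adjusted p = 2.6e-05). Of 27 class switch and hypermutation genes 22 rose and 1, Parp3, fell, and Batf (3.43 ± 0.128, adjusted p = 3.5e-06) and Exo1 (3.50 ± 0.174, adjusted p = 7.2e-06) had the lowest adjusted p. Ribosome biogenesis genes rose in 23 of 24 cases, as in Dkc1 (1.70 ± 0.134, adjusted p = 3.4e-05). Of 20 glycolysis and nutrient uptake genes 15 rose, such as Gapdh (2.63 ± 0.106, adjusted p = 4.2e-06), and 4 fell, Myc (-2.09 ± 0.124, adjusted p = 1.3e-05), the glucose transporter Slc2a1, Slc3a2 and Hif1a.

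Among genes of the resting state, 23 of 28 B cell identity and follicular genes fell and 2, Id3 and Pou2af1, rose. Ccr7, a homing receptor (-3.44 ± 0.0915, edgeR adjusted p = 1.8e-06), and Cr2, complement receptor 2 (-2.18 ± 0.13, adjusted p = 1.3e-05), fell. Of 16 marginal zone B cell genes 12 fell, including Cd1d1 (-2.44 ± 0.106, adjusted p = 5.3e-06) and the Notch target Hes1 (-4.59 ± 0.223, adjusted p = 6.7e-06), and 3 rose. All 20 immediate early and stress genes fell, such as Nr4a1 (-6.16 ± 0.197, adjusted p = 2.2e-06) and Fosb (-5.96 ± 0.135, adjusted p = 1.3e-06). The 27 NF-kB and TLR4 response genes were divided, with 11 falls, among them Rel (-2.24 ± 0.0977, adjusted p = 5.3e-06) and the activation marker Cd69 (-2.27 ± 0.093, adjusted p = 4.4e-06), and 9 rises. Of 27 interferon response genes 9 rose, such as Gbp3 (1.62 ± 0.145, adjusted p = 5.6e-05), and 1, Rsad2, fell (-5.35 ± 0.31, adjusted p = 1.2e-05). Of the 12 B-1 and CD43-positive B cell genes 3 rose, including Spn (3.01 ± 0.188, adjusted p = 1.5e-05), which encodes CD43, and 6 fell, and the median (-0.58) and mean (0.03) of the list differed in sign. Of the 17 IgH locus neighbours 9 fell and 4 rose. Both measured light chain constant genes rose, Igkc (1.37 ± 0.179, adjusted p = 0.00035) and Iglc2 (0.57 ± 0.182, adjusted p = 0.025). Of the 6 IgH constant genes tested 3 rose, Ighm (1.58 ± 0.126, adjusted p = 3.4e-05), Ighg2b and Ighg3, and 1, Igha, fell (-4.51 ± 0.241, adjusted p = 8.7e-06). The IgG rises did not hold in each genotype. Stimulated over resting, Ighg3 was 3.42 in wild-type, 17.2 in hs3b-hs4 deletion, 1.06 (0.966 to 1.17) in 3'PAL deletion and 0.218 (0.00461 to 1.95) in 3'RR deletion cells. Ighg2b was 3.04, 1.46, 5.7 and 0.436 (0.0998 to 1.51) in the same order.

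Markers of other cells fell with culture beside these groups. Of 17 monocyte and macrophage genes 15 fell, led by Vcam1 and C1qb, and 10 of 11 erythroid genes fell while Tfrc, the transferrin receptor that dividing cells also use, rose. The falls were 8 of 10 for dendritic cells, where 1 rose, 6 of 6 for megakaryocytes and platelets, 5 of 9 for T cells, 3 of 3 for NK cells, 3 of 3 for neutrophils and 5 of 6 for endothelial and stromal cells. Of the 4 sex-linked genes measured, which were left out of the list test, 1 fell, Ddx3y (-0.80 ± 0.0895, edgeR adjusted p = 0.00016).

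The limma camera test over 24 lists, with a preset correlation of 0.01 between genes, called 19 lists, 8 up and 11 down. The adjusted p was 2.4e-20 for cell cycle (adjusted p = 0.25 with an estimated correlation), 1.5e-26 for cholesterol synthesis (adjusted p = 0.18 with an estimated correlation), 5.1e-10 for the secretory pathway (adjusted p = 0.22 with an estimated correlation) and 2.9e-07 for both ribosome biogenesis and class switching (adjusted p = 0.37 and 0.27 with an estimated correlation). It was 7.6e-05 for plasmablast genes (adjusted p = 0.25 with an estimated correlation), 0.01 for plasma cells (adjusted p = 0.35 with an estimated correlation) and 0.00012 for glycolysis (adjusted p = 0.27 with an estimated correlation). Among the lists called down it was 4.2e-07 for B cell identity (adjusted p = 0.25 with an estimated correlation), 2.5e-16 for immediate early genes, 1.3e-06 for marginal zone genes, 2.8e-22 for macrophages, 0.0012 for dendritic cells, 0.019 for T cells and 0.0071 for endothelial cells (each adjusted p = 0.22 with an estimated correlation). The remaining lists called down were erythroid cells at 1.9e-12 (adjusted p = 0.11 with an estimated correlation), megakaryocytes at 0.00014 (adjusted p = 0.27 with an estimated correlation), NK cells at 0.0071 (adjusted p = 0.25 with an estimated correlation) and NF-kB and TLR4 at 0.049 (adjusted p = 0.44 with an estimated correlation). All 19 calls were therefore lost with an estimated correlation. Neutrophils (adjusted p = 0.072), interferon response (0.3), light chain genes (0.29), IgH neighbours (0.29) and B-1 genes (0.92) were not called with the preset correlation either. Counts adjusted over the list alone were those given, except for the IgH constant genes, where 2 rose and 1 fell adjusted over the list alone.

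**Figure D3:**
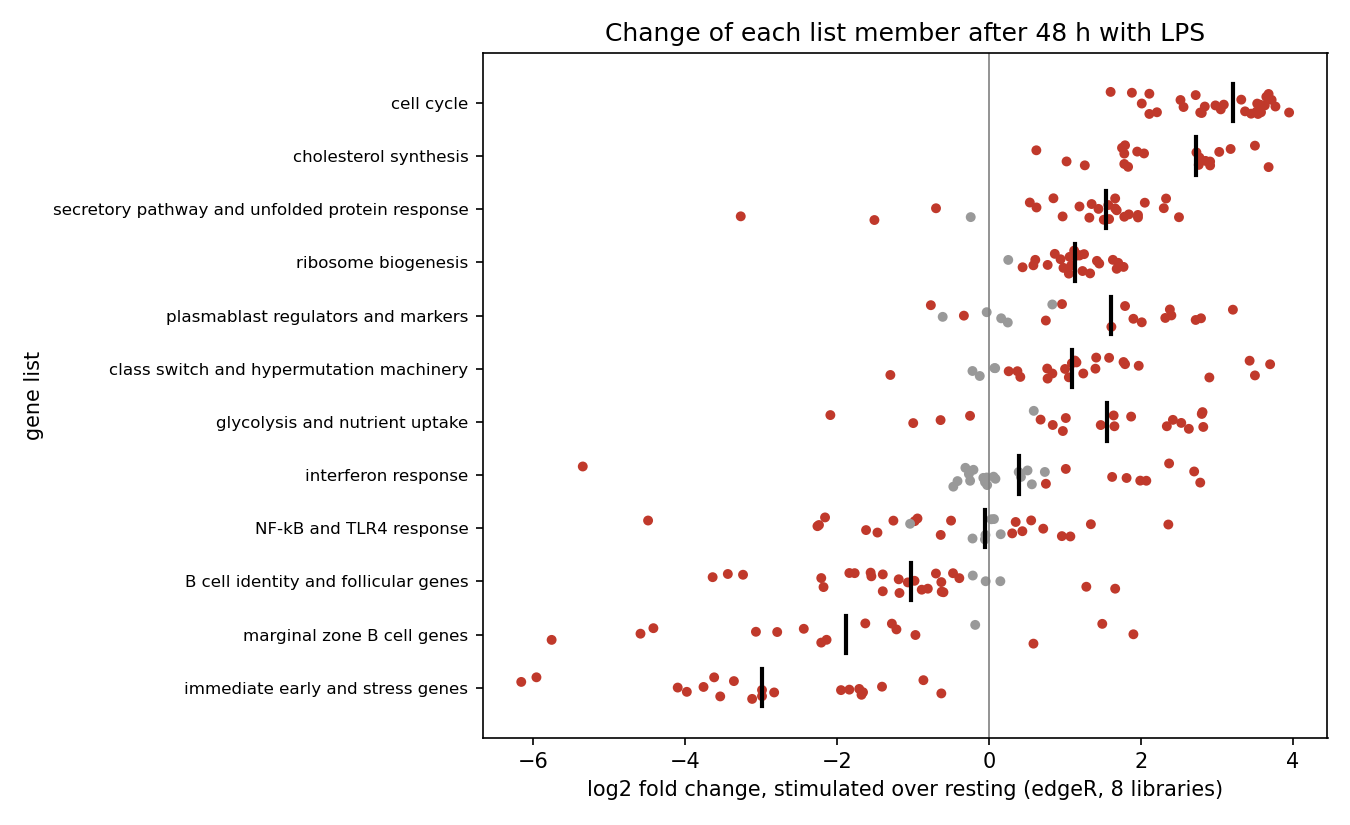
Log2 fold change of each measured member of 12 gene lists after stimulation (edgeR, 8 libraries; red, adjusted p under 0.05; grey, not called; black bar, median of the list). All 30 cell cycle genes and all 21 cholesterol synthesis genes lie to the right of 0, and all 20 immediate early and stress genes to the left.

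Each mutant was tested over both states with the same fit, comparing its 2 libraries with the 2 wild-type libraries. In 3'RR deletion cells all 6 IgH constant genes tested fell, also when adjusted over the list alone. Ighm fell by 1.29 on the log2 scale (SE 0.177, edgeR adjusted p = 0.015), Ighg2c had a log2 fold change of -8.52 ± 0.682 (adjusted p = 0.00169) and Igha of -1.82 ± 0.335 (adjusted p = 0.0459). Erythroid and macrophage markers rose, 8 of 11 and 7 of 17 (10 and 14 adjusted over the list alone), such as Slc4a1 (4.43 ± 0.212, adjusted p = 0.00027), the adhesion gene Vcam1 (2.36 ± 0.243, adjusted p = 0.00482) and the complement gene C1qb (1.96 ± 0.252, adjusted p = 0.0119). Slc4a1, Vcam1 and C1qb were each below 1 CPM in the stimulated libraries, so these calls rest on the resting ones, as do those of Rhd, Tmcc2 and Epb4.2. Rsad2 of the interferon list (2.79 ± 0.416, adjusted p = 0.0215), Ctla4 of the B-1 list (2.05 ± 0.315, adjusted p = 0.024) and Cd8a of the T cell list (2.01 ± 0.369, adjusted p = 0.0455) also rose. No gene of the cell cycle, ribosome biogenesis, secretory pathway or plasmablast list was called over all genes, although 9 plasmablast genes rose and 1 fell adjusted over the list alone.

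Altogether 290 genes were called in 3'RR deletion cells (136 higher, 154 lower; 2009 at an unadjusted p under 0.05), and 56 of them were immunoglobulin or T cell receptor gene segments, 11 of them higher. The 5 largest rises were the red cell genes Rhd, Tmcc2, Epb4.2 and Slc4a1 and the antiviral factor gene Trim5, with log2 fold changes from 4.26 to 4.63. Among genes with a mean log2 CPM of at least 3, the 5 largest falls were Rprl3, Ftl2, Ighg3, Rps3a3 and Ighg2b. Rps3a3, a copy of a ribosomal protein gene, stood at 1.74 and 2.425 CPM in 3'RR deletion cells against 359 and 629.5 CPM in wild-type cells, and Ftl2, a copy of the ferritin light chain gene, at no more than 0.0696 CPM in the 3'RR deletion libraries against 70.5 and 52.8 CPM. Reads of such copies can be split with their parent genes, so their levels are uncertain. The count was 124 (26 higher) without the wild-type resting library and 76 (14 higher) without the 3'RR deletion resting library, whose globin level was 12538 CPM. Of the 10 genes named, Ftl2, Rps3a3 and Ighg2b stayed called without either library. For the 3'RR deletion over both states it was 529 with DESeq2 and 657 without the low-count filter.

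Within each state, with 1 library on either side and no test, differences were ranked by size (log2 ratio of at least 1 and at least 10 CPM in the higher library). In resting 3'RR deletion cells 476 genes passed this rule (355 higher, 121 lower), and in stimulated cells 270 (154 higher, 116 lower), of which 70 were immunoglobulin or T cell receptor segments. Trim12a, of the same antiviral gene family as Trim5, was highest in rank in both states, at 83.7 CPM against 0.666 CPM in resting and 38 CPM against 0.0719 CPM (2 counts) in stimulated cells. Trim30d followed in stimulated cells (48.9 against 2.01 CPM), with Hbb-bs and Hba-a1, and Aqp1, Slc4a1 and Tmcc2 in resting cells. Lowest in rank were Rps3a3, Ftl2 and Rpl34-ps1 in both states, with Col6a4, a collagen gene, in resting cells (1 count, 0.0348 against 31.4 CPM) and Ighg3 in stimulated cells (1 count against 2772). As lists, resting 3'RR deletion cells held more erythroid (median log2 ratio 2.7, 11 of 11 members higher), macrophage (1.6, 17 of 17) and cell cycle transcripts (0.73, 30 of 30) than wild-type cells. In stimulated cells the plasma cell list (0.86, 6 of 6 higher), the interferon list (0.6, 21 of 27 higher) and the plasmablast list (0.52, 16 of 19 higher) stood higher, while all 24 ribosome biogenesis genes were lower (median -0.25). Erythroid (1.2, 9 of 11 higher), macrophage (0.33, 16 of 17 higher) and B cell identity genes (0.36, 22 of 28 higher) also stood higher there. Some macrophage markers were close to absent in stimulated cells, such as Csf1r (0.53 against 0 CPM) and Vcam1 (0.114 against 0 CPM). Their count of higher members thus rests in part on few reads. These list medians are ratios between 2 libraries and carry no error over animals.

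In hs3b-hs4 deletion cells, over both states, Ftl2 (-11.31 ± 0.476, edgeR adjusted p = 0.00055) and Serinc3, a membrane protein gene (-3.02 ± 0.249, adjusted p = 0.013), fell most among genes with a mean log2 CPM of at least 3, followed by Emb, which encodes the adhesion glycoprotein embigin (-2.06 ± 0.184, adjusted p = 0.019), and Abhd2 (-1.10 ± 0.129, adjusted p = 0.037). Of the IgH constant genes Ighg2c, below that level, fell (-3.72 ± 0.433, adjusted p = 0.0374), and 3 of 6 fell adjusted over the list alone. Slc4a1 (1.79 ± 0.197, adjusted p = 0.029), at 57.4 against 16.3 CPM in resting cells and near 0 in stimulated cells of both genotypes, and the ferritin light chain gene Ftl1 (1.60 ± 0.155, adjusted p = 0.021) rose. Ftl1 and Ftl2 resemble each other, so reads may be split between them. Slc4a1 was the only erythroid gene of 11 called (7 adjusted over the list alone), no plasma cell gene was called (5 adjusted over the list alone), and no other list had a called member. In all, 21 genes were called (11 higher, 10 lower; 1303 at an unadjusted p under 0.05; 185 with DESeq2). The count was 7 without both 3'RR deletion libraries, 6 without the wild-type resting library, 1 without the hs3b-hs4 deletion resting library and 37 without both 3'PAL deletion libraries. Ftl2 stayed called without either resting library, while Serinc3 and Emb stayed called only without the wild-type one. It was 179 in a fit to the 4 hs3b-hs4 deletion and wild-type libraries alone.

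By the size rule 302 genes differed in resting hs3b-hs4 deletion cells (177 higher, 125 lower) and 122 in stimulated cells (53 higher, 69 lower). The resting rises were led by Atp9a, a phospholipid flippase gene (17.1 against 0.973 CPM), Prg2, H60b and Igj (877 against 124 CPM), and the falls, beside Ftl2, by Pydc4, an interferon-inducible gene (1.62 against 91.9 CPM), Eps8l1 (0.0771 CPM, 2 counts, against 29.3 CPM) and Ighg3. All 48 immunoglobulin segments that passed in resting cells were higher. In stimulated cells Trim12a (13.5 against 0.0719 CPM), Ptpn14, a tyrosine phosphatase gene (21.2 against 1.9 CPM), Trim30d and Atp9a were higher, and Ftl2, Serinc3 (68.2 against 702.2 CPM), Emb (12.8 against 69.6 CPM) and Ighg2b (7.66 against 40.9 CPM) lower. The interferon list stood lower in resting hs3b-hs4 deletion cells (median log2 ratio -0.72, 23 of 27 members lower) and higher in stimulated ones (0.63, 25 of 27 higher). Markers of other cells also differed in resting cells, with erythroid (1.7, 11 of 11 higher) and macrophage markers (0.69, 15 of 17 higher) higher and megakaryocyte markers (-0.7, 6 of 6 lower) lower. Erythroid markers stood higher in stimulated cells too (0.34, 9 of 11 higher). The plasma cell list was higher in resting (0.89, 6 of 6) and in stimulated cells (0.37, 6 of 6). All 20 glycolysis genes were lower in stimulated cells (median -0.26), whereas 17 of 20 were higher in resting cells (0.21).

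In 3'PAL deletion cells, over both states, Ftl2 (-11.33 ± 0.474, edgeR adjusted p = 0.00047) and Serinc3 (-2.75 ± 0.247, adjusted p = 0.0089) fell most among genes with a mean log2 CPM of at least 3, with Dhdh (-1.50 ± 0.182, adjusted p = 0.023), Naip2, a sensor of bacterial secretion systems (-1.28 ± 0.159, adjusted p = 0.024), and Pkig, an inhibitor of protein kinase A (-1.27 ± 0.154, adjusted p = 0.023). Ighg2c, below that level, was the only IgH constant gene of 6 to fall (-3.14 ± 0.413, adjusted p = 0.0304), also adjusted over the list alone. The 5 largest rises were Aqp1, Tmcc2, Epb4.2, Slc4a1 and Trim10, all expressed in red cell precursors, with log2 fold changes from 4.29 to 5.17 that rest on the resting libraries, since each was below 1 CPM in stimulated cells. Of 11 erythroid genes 7 rose (10 adjusted over the list alone), and Ctla4 of the B-1 list rose (2.23 ± 0.315, adjusted p = 0.0376; 4 of the list adjusted over the list alone). The total was 79 genes (51 higher, 28 lower; 1380 at an unadjusted p under 0.05; 257 with DESeq2; 313 without the low-count filter). It was 3 without the wild-type resting library, 13 without the 3'PAL deletion resting library and 39 without both 3'RR deletion libraries. Ftl2 stayed called without either resting library, while Serinc3 and Pkig stayed called only without the 3'PAL deletion one. Since Ftl2 fell in all 3 mutants, its fall is not particular to the 3'PAL deletion.

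By the size rule 296 genes differed in resting 3'PAL deletion cells (191 higher, 105 lower), but 131 were higher and 156 lower with scaling by library size alone, so the direction of the balance rests on the scaling. In stimulated cells 237 genes differed (186 higher, 51 lower). Tmcc2, Slc4a1 and Aqp1 were among the largest resting rises, and the globin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt were the largest stimulated ones. Lowest in rank, beside Ftl2, were Pydc4 (1.06 against 91.9 CPM), Eps8l1 (0.895 against 29.3 CPM) and Hmgb1-ps8 (no count, against 10.4 CPM) in resting cells, and Serinc3 (78.1 against 702.2 CPM), Zfp429 (0.913 against 11.9 CPM) and Pydc4 in stimulated cells. Stimulated 3'PAL deletion cells had higher interferon response transcripts (median log2 ratio 1.1, 25 of 27 higher, 17 of them at least 2-fold) and immediate early transcripts (0.81, 19 of 20 higher). Their ribosome biogenesis (-0.57, 24 of 24 lower) and cell cycle transcripts (-0.47, 29 of 30 lower) were lower than in stimulated wild-type cells. The plasma cell list (0.64, 6 of 6 higher), the plasmablast list (0.49, 14 of 19 higher) and erythroid markers (0.42, 8 of 11 higher) stood higher in stimulated 3'PAL deletion cells. Stimulated 3'RR and hs3b-hs4 deletion cells also had higher interferon (0.6 and 0.63) and plasma cell lists (0.86 and 0.37). Ribosome biogenesis was lower in both (-0.25 and -0.13). These ratios share the stimulated wild-type library, so its own deviations cannot be told apart from an effect of each deletion. In resting 3'PAL deletion cells markers of other cells differed, with erythroid markers higher (2.8, 11 of 11 higher) and megakaryocyte (-0.89, 6 of 6 lower) and macrophage markers (-0.2, 15 of 17 lower) lower. In the same library interferon (-0.58, 22 of 27 lower) and immediate early transcripts (-0.13, 13 of 20 lower) were lower, and cell cycle transcripts (0.5, 29 of 30 higher) were higher, while ribosome biogenesis transcripts (0.11) lay within the range of random lists, at the percentile 80.

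The last comparison set the genotypes without hs3b and hs4 (3'RR and hs3b-hs4 deletion) against those with both (wild-type and 3'PAL deletion), 2 libraries each, within each state. In stimulated cells 0 genes were called by edgeR (391 at an unadjusted p under 0.05; 8 without the filter; 7 with DESeq2; smallest adjusted p = 0.14), in resting cells 0 (853 unadjusted; 71 without the filter; 73 with DESeq2; smallest adjusted p = 0.34), and for the difference between states 0 (300 unadjusted; 2 with DESeq2). Ighg2b in stimulated cells (log2 fold change -3.77 ± 1.45, adjusted p = 1) and Ighg3 in resting cells (-5.37 ± 1.9, adjusted p = 0.84) were lower by fitted value without passing, and Ighm in stimulated cells differed little on average (-0.16 ± 0.628, adjusted p = 1), since it was low in 3'RR deletion and not in hs3b-hs4 deletion cells. The lowest adjusted p belonged to Emb in stimulated cells, chosen after its value was seen (-2.43 ± 0.209, adjusted p = 0.14), at 14.6 and 12.8 CPM in the 2 genotypes without the enhancers and 69.6 and 78.2 CPM in the others. Chance would give 737 genes at an unadjusted p under 0.05 in each comparison. That exceeds the 391 in stimulated cells and the 300 for the difference between states, but not the 853 in resting cells. With 2 libraries a side the test found 56.1% of simulated 4-fold changes in stimulated and 68.2% in resting cells, so changes of this size may have been missed.

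In stimulated cells the camera test with the preset correlation called 7 of 24 lists without hs3b and hs4. Glycolysis and nutrient uptake (median log2 fold change -0.27, adjusted p = 5.6e-10; adjusted p = 0.63 with an estimated correlation), cholesterol synthesis (-0.14, adjusted p = 3e-04; adjusted p = 0.63 with an estimated correlation) and immediate early genes (adjusted p = 0.035; adjusted p = 0.65 with an estimated correlation) were lower. B cell identity (adjusted p = 0.0052), macrophages (8.6e-05), plasma cells (0.04) and T cells (0.03) were higher (each adjusted p = 0.63 with an estimated correlation). All 7 calls were lost with an estimated correlation, and no member gene passed on its own.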

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

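The tests on admixture as a source of the falls, on pseudogenes, on scaling, on plasmablasts and on the 3'PAL deletion were chosen only after their results were seen.

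Of 76 groups of 4 libraries examined, 8 had a library far from the other 3, where chance gives 3.8. A flagged value on its own therefore carries little weight. Several of the values below single out the wild-type resting library, however. That library is the reference of every resting mutant ratio, so those ratios share its deviations. In wild-type resting cells AY036118 took 1.94% of the gene counts, far above the other resting libraries. Lars2 took 15.4% of the estimated transcript counts of the same library, also far above the others. Ighg2c stood at 10.9 CPM in wild-type resting cells, above the 3 mutants. Iglc2 was highest in hs3b-hs4 deletion resting cells, at 275 CPM. The mean log2(CPM + 1) of the secretory pathway list was lowest in wild-type resting cells, at 6.34, and that of the B-1 list was lowest there too, at 3.08. The class switch list had its lowest mean among stimulated libraries in 3'PAL deletion cells, at 5.66. The hs3b-hs4 deletion library had the lowest total among stimulated libraries, 25.6 M counts (25596608). The entry without a gene name, used in no comparison, reached 8774 counts in resting 3'PAL deletion cells.

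The 290 genes called in 3'RR deletion cells over both states were set against 3 technical explanations. Dilution by erythroid cells and macrophages in the resting pool would lower B cell transcripts alike. After TMM scaling the B cell identity list stood at 0.022 in resting cells, with 0 of 28 members at least 2-fold lower. TMM scaling centres most genes and can remove an even dilution, so this value cannot decide on dilution. The median log2 fold change of the falls, -2.91, cannot decide on it either, since 151 of 154 called falls were at least 2-fold and smaller changes were rarely called. Admixture may explain part of the rises: 74 of 136 (54.4%) were also at least 1 CPM and 1.5 times wild-type in stimulated cells, so for the rises admixture and deletion cannot be told apart with 1 library per state, although a gradient and CD43 selection were used. Pseudogenes were overrepresented among the falls: 52 of 92 falls with a gene type outside the immunoglobulin genes were pseudogenes, against 822 of 13655 other genes (odds ratio 20.3, Fisher's exact test p = 2.3e-38). The Fisher test treats genes as independent, yet all come from the same pools, so its p does not cover variation between animals. The overrepresentation does not decide for reads shared with parent genes as the cause. Such reads are shared in every library, so sharing alone would not lower a copy in some genotypes only, and the test does not part it from strain background. Ftl2 fell in all 3 mutants, so its fall sets wild-type apart and cannot be credited to a single deletion. Strain background, from segments of the genome that differ on the mixed background, also cannot be told apart from the deletion: 70 of 227 called genes outside the immunoglobulin loci had another called gene within 1 Mb, where random draws gave a median of 68 and at most 99. A biological effect of the deletion on these genes stays open and was not tested apart from these.

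Stimulated 3'RR deletion cells had less Ighm and more Igkc than wild-type cells. Scaling between libraries cannot give this, since the ratio of Ighm to Igkc within the library was 5.1 times higher in wild-type cells. More plasmablasts alone would raise both transcripts, yet Ighm was at most 0.376 times wild-type over 4 scalings or quantifications, which leaves open more plasmablasts with less Ighm in each cell. Another IgH allele read less well against the reference cannot be told apart. The rank correlation of IgH V segment counts with stimulated hs3b-hs4 deletion cells, which kept Ighm, exceeded that with wild-type by 0.046 (bootstrap interval 0.02 to 0.079). The difference for 3'PAL deletion cells was 0.012 (-0.0075 to 0.035). In resting cells the correlation was 0.945 with hs3b-hs4 deletion, 0.955 with 3'PAL deletion and 0.943 with wild-type. The bootstrap resampled segments and does not cover variation between pools, so these values do not decide it. Loss of enhancer activity in the 3'RR deletion may be the cause and was not tested apart from an allele effect.

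Ighg2c was low in all 3 mutants. If the mutants carried another IgH allotype, in which this gene is replaced by a relative, their V segment counts could resemble each other more than wild-type, but the smallest rank correlation between mutants was lower than the largest with wild-type (difference -0.036 in stimulated cells), which does not decide it since recombination could separate V and constant genes. Loss of enhancer activity in 3'PAL deletion cells cannot be told apart either: in stimulated cells Ighg2b was 1.6 times wild-type, but Ighg3 was 0.352 times, Ighg1 0.557 times, Ighm 0.679 times and the summed IgG genes 0.685 times (0.654 to 0.718) wild-type, and reads may be split between IgG genes.

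The stimulation result was set against other splits of the 8 libraries. Within genotypes, 8 splits are too few for a share under 0.05: the real split gave 10282 genes and the highest other 0. Without the genotype term, the real split was 1 of 35 and gave 9944 genes, while the highest other gave 1. These 35 splits ignore that each genotype gave 1 library of each state. They make chance unlikely for that fit only and do not exclude it for the fit with the genotype term.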

How the results depend on the processing

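For the mutants over both states, leaving out a single resting library was chosen only after the results were seen, as was removing markers of other cell types within a state. Of 124 alternative values of the main counts and list tests 97 stayed within 1.5 times the reported value and 27 did not. Stimulation stayed between 9055 and 10453 genes under every alternative run. Scaling by DESeq2 size factors, TMM without immunoglobulin genes and kallisto counts moved none of the main counts past that limit. With the DESeq2 Wald test the count was 529 for the 3'RR deletion over both states, 185 for the hs3b-hs4 deletion over both states and 257 for the 3'PAL deletion over both states, and 7 (stimulated), 73 (resting) and 2 (difference between states) without against with hs3b and hs4. DESeq2 kept 270 of 290, 21 of 21 and 74 of 79 genes of the mutants. With no low-count filter the counts were 657, 189 and 313 for the mutants, and 8 (stimulated) and 71 (resting) without hs3b and hs4. The fit to only the mutant and wild-type libraries gave 179 genes for the hs3b-hs4 deletion. Leaving out libraries gave 76 to 338 genes for the 3'RR deletion, 1 to 37 for the hs3b-hs4 deletion, 3 to 71 for the 3'PAL deletion and 0 for each comparison without against with hs3b and hs4; a genotype and state without its library is assumed to vary like the others. With a minimum of 20 CPM the size rule gave 314 (3'RR deletion resting), 195 (hs3b-hs4 deletion resting), 80 (hs3b-hs4 deletion stimulated) and 187 (3'PAL deletion resting) genes, since fewer genes can pass. With an estimated inter-gene correlation 0 of 19 lists stayed called for stimulation and 0 of 7 without hs3b and hs4. With library size only, Ighg3 in resting 3'PAL deletion cells was 0.993 times wild-type, reversed from 1.13, and the size rule there gave 131 rises and 156 falls, as this scaling shifted the median of all genes by -0.11 on the log2 scale. Of 1837 values of named genes under alternatives 1708 were the same, 77 lost and 8 gained a call, 43 moved and 1 reversed. Leaving out a resting library ended most calls of genes named for the mutants: 18 were lost and 8 stayed without wild-type, 7 were lost and 3 stayed without 3'RR deletion, 5 were lost and 1 stayed without hs3b-hs4 deletion, and 7 were lost and 3 stayed without 3'PAL deletion resting cells. Apart from these constructions the cause was not tested.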

Other observations

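No test or alternative was added for the values below, which were chosen after they were seen and are reported without explanation.

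Trim12a, Trim5 and Trim30d, neighbours on chromosome 7, differed between states within a genotype. Trim12a was at 83.7 and 38 CPM in resting and stimulated 3'RR deletion cells, at 0.347 and 13.5 CPM in hs3b-hs4 deletion cells and below 1 CPM in the other 4 libraries. Trim30d showed the same order in hs3b-hs4 deletion cells, with 2.58 CPM in the resting and 21.8 CPM in the stimulated library, as did Trim5, with 1.12 and 8.14 CPM.

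Serinc3 on chromosome 2 was at 127.4 and 158.5 CPM in resting hs3b-hs4 and 3'PAL deletion cells and at 805.4 and 754.2 CPM in resting wild-type and 3'RR deletion cells. Atp9a was at 17.1 and 13.9 CPM in the first pair and 0.973 and 0.87 CPM in the second, and Ptpn14 at 109.2 and 94.3 against 19 and 22.7 CPM. Emb on chromosome 13 was low in the 3'RR and hs3b-hs4 deletion libraries, at 12.8 to 16.5 CPM, against 52.9 to 78.2 CPM in the others.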
